A study of Homo sapiens with 15 samples.

How the data were processed

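CIITA ChIP-seq of Raji cells was analysed from 5 peak lists and the series table of merged sites, all as deposited. Per the submitters' processing notes, the authors used Bowtie, HOMER and the build hg19; versions, peak thresholds and the control library are not given in the sources used here. Each library had its own list, so peaks were treated as called per library. Peaks had a single width per list, 193 bp for the Boss Lab antibody, 197 and 195 bp for Rockland, 197 and 209 bp for Diagenode. The deposited lists hold a score column that is 1 on every line and so ranks nothing. Per the file headers, the series table gives the authors' X-Y box motif score, whose scale is not stated and which can be negative, the matched sequence, the distance to the nearest TSS and a chromatin state of GM12878, another B cell line. Per the labels' protocols, the Boss Lab library was prepared by a different ligation procedure from the kit used for the Rockland and Diagenode libraries, so antibody and preparation cannot be separated there.

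Samples were grouped by the titles. Peaks overlapping by at least 1 bp were merged across lists. Marks of the series table matched the list overlaps at all 480 sites, and 1 site had no score. Pairwise overlap was compared with 1000 random placements on the same chromosomes, without chromosome M, with Benjamini-Hochberg adjustment over 10 pairs. Site counts were compared with 1000 placements of all lists. Shares were compared by two-sided Fisher's exact tests, 16 in all and adjusted together, all of them past 0.05, and scores by 100000 permutations of the difference in medians with 10000 bootstrap draws. Sites are not replicates, and intervals cover counting error only. A gene counted as having a site where it was the nearest gene of a table site within 10 kb of the TSS. The 11 gene lists were matched by Entrez number to 29989 genes with a transcript in a RefSeq table of GRCh38.p14, used for names alone; 458 of 459 numbers of the series table and all 101 list genes were found. Chromosome lengths for random placement were entered from general knowledge of hg19. Tests were first run on simulated data: 48 of 48 planted overlaps were found for the pair of Rockland 2 and Diagenode 2, and for 53 against 426 sites a score shift of 5 was called in 40 of 40 runs and a shift of 0 in 1 of 40. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

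Groups, tests, gene lists and most alternatives were fixed before the data were examined. Several plans could not be kept. With a constant peak score, the rank agreement of peak scores and the alternatives on higher-scoring peaks were not run; the first 50% of each list in file order was used in their place, although the sources used here do not say that the order is a ranking. Single-library sites carry no annotation, so the promoter comparison set sites in 3 or more libraries against sites in 2, and such sites have no gene names. Without an hg19 genome the motif search was replaced by the authors' score. The 10 libraries of other marks, in 6 groups, were not used here, so the comparison of Raji with RJ2.2.5 was not made.

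The result of the list for MHC class I and peptide loading and the overlap with super enhancers are not reported here. Named genes were the list genes with a site and then the nearest genes of up to 25 further sites in the order of the number of libraries. Ties were to be broken by peak score and were broken by motif score instead, a choice made after the files were seen; the highest-scoring peak of each library alone could not be taken. SLC25A53 was named after its value was seen. Alternatives were the overlap rule (at least 50% of both peaks or of the shorter, or centres within 500 bp), each library left out, recurrence at 2 libraries, promoters within 5 kb, the extended MHC region from 25.7 to 33.4 Mb of chromosome 6 in place of the class II region from 32.2 to 33.4 Mb, and list windows of 1 and 50 kb. Chosen after the data were seen were the score comparisons with their alternatives, peaks moved by 5 to 50 kb, the first part of each list, lists from sites of at least 3 libraries or 2 antibodies, and omission of sites absent from the series table.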

Results

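The series measured where CIITA sits on chromatin in Raji cells, a human B cell line from a Burkitt lymphoma. CIITA is the class II transactivator, a coactivator without a DNA-binding domain of its own that is recruited to MHC class II promoters by factors bound to their X and Y boxes. The labels list 15 samples in Raji and in RJ2.2.5, a Raji derivative that lacks functional CIITA. Peak lists of 5 Raji CIITA ChIP libraries were analysed, made with 3 antibodies: 1 library with an antibody of the Boss laboratory, 2 with a Rockland antibody and 2 with a Diagenode antibody. The lists held 2307 peaks for the Boss Lab antibody, 80 and 122 for Rockland replicates 1 and 2, and 421 and 2168 for Diagenode replicates 1 and 2. The deposited series table held 480 hg19 sites marked in at least 2 of these libraries, with the nearest gene and a motif score for the X and Y boxes. H3K27ac, H3K4me3, input and ATAC libraries were not analysed here, so no value below compares Raji with RJ2.2.5. Read depths were unknown, and nothing in the labels said that replicates came from separate cultures.

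Genes of the MHC class II pathway carried most of the sites found in every library, 13 of 20 of which lay in the MHC class II region of chromosome 6. Of 10 classical MHC class II genes, 7 had a site within 10 kb of the TSS in the series table, which were HLA-DRA, HLA-DRB1, HLA-DRB5, HLA-DQA1, HLA-DQB1, HLA-DPA1 and HLA-DPB1. All 5 accessory genes had one, namely CD74, the invariant chain, HLA-DMA and HLA-DMB, which form the peptide exchange factor, and HLA-DOA and HLA-DOB, which form its modulator. Among all other annotated genes 1.35% and 1.36% were the nearest gene of such a site. Fisher's exact test, one-sided and Benjamini-Hochberg adjusted over 11 lists, gave adjusted p = 1.12e-10 for the classical genes and 2.63e-09 for the accessory genes. The HLA-DRA promoter site on chromosome 6 (32407425 to 32407645, 84 bp from the TSS, active promoter state in GM12878 cells) had peaks in all 5 libraries and the motif score 39.7. The promoter sites of HLA-DRB5 (194 bp from the TSS), HLA-DPA1 (77 bp), HLA-DMA (95 bp), HLA-DMB (62 bp) and CD74 (70 bp, chromosome 5, 149792457 to 149792681) also had peaks in all 5 libraries. Whether Raji cells carry HLA-DRB5 was not checked, and reads shared with related class II genes stay open at its site. Promoter sites of HLA-DRB1, HLA-DQA1 and HLA-DOA had peaks in 4 libraries, with Diagenode replicate 1 missing. Those of HLA-DQB1 and HLA-DOB had peaks with the Boss Lab antibody and Diagenode replicate 2, and that of HLA-DPB1 with the Boss Lab antibody and Rockland replicate 2. The table credits each site to its nearest gene, so genes that share a promoter region are not all counted.

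Sites more than 1 kb from an annotated TSS in this region were recurrent too. Sites 14882 bp and 20173 bp from the HLA-DRB1 TSS and 14087 bp from HLA-DQA1 had peaks in all 5 libraries. So did sites 1796 bp (score 29.2) and 23757 bp from HLA-DQB1. Sites 19956 bp and 9383 bp from HLA-DOA and 33825 bp from HLA-DRA had them too. Those nearest to HLA-DRB1 carried the active promoter state of GM12878, and the others enhancer states. Counted over merged sites, the MHC class II region held 19 of 56 sites found in 3 or more libraries (33.9%, Clopper-Pearson 95% interval 21.8 to 47.8%) and 8 of 4001 single-library sites (0.200%, 0.0864 to 0.394%). The odds ratio was 252 (95% interval 98.2 to 711, two-sided Fisher's exact test, adjusted p = 2.48e-30 over 16 share tests). It was 28.9 with recurrence set at 2 libraries, 48.1 for the extended MHC region and 136 for the first 50% of each list in file order, all past the threshold. Neighbouring sites are not independent, so p-values over sites are too small.

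**Figure D1:**
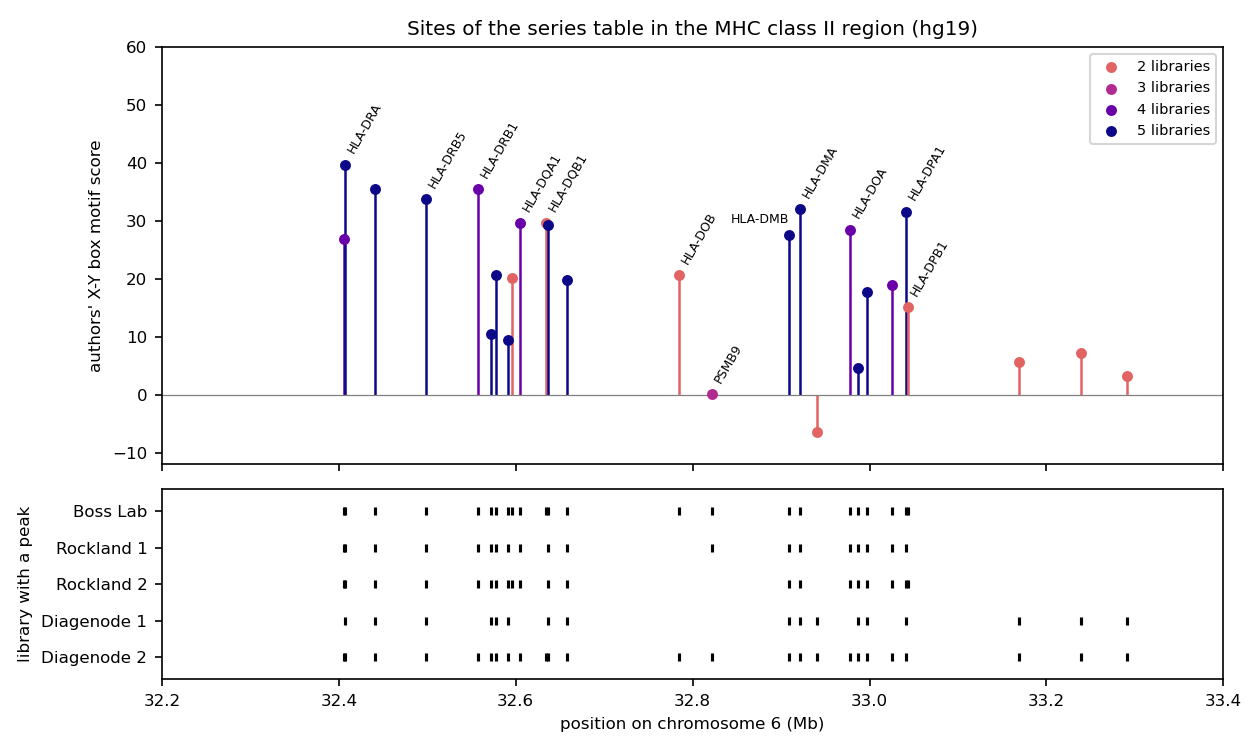
Sites of the series table in the MHC class II region of chromosome 6, by position in Mb (hg19). The upper panel gives the authors' X-Y box motif score of each site, coloured by the number of libraries with a peak and named by gene where the site lies within 1 kb of a TSS and was found with at least 2 antibodies; the lower panel marks the libraries with a peak. The HLA-DRA promoter had the score 39.7 and peaks in 5 libraries.

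The other gene lists gave mixed counts. HLA-E and HLA-F, MHC class I genes, had promoter sites with the Boss Lab antibody and Diagenode replicate 2, and PSMB9, an immunoproteasome subunit, had a site in 3 libraries. Of 10 housekeeping genes, which served as a comparison list, ACTB, RPL13A, EEF1A1 and PPIA had a site (exact adjusted p = 2.53e-05), each found in the 2 Diagenode libraries and in no other. Sites of this kind drop out by construction without either Diagenode replicate and among sites of at least 2 antibodies. The count of 0 of 10 in those settings is therefore no separate evidence. RFX5, a subunit of the complex that binds the X box, had a promoter site in all 5 libraries with the score 14.9, the sole hit among 8 X and Y box binding factors and CIITA itself (exact adjusted p = 0.192). RAB4B, a small GTPase gene on chromosome 19, had a site in 3 libraries with the score 32.1, the sole hit among 6 non-MHC genes linked to CIITA in earlier work (exact adjusted p = 0.175). Both of these lists, each by its 1 gene, passed the threshold among sites of at least 2 antibodies, an alternative chosen after the data were seen. The exact adjusted p was 0.0470 for the RAB4B list and barely under the threshold for the RFX5 list. Leaving out Diagenode replicate 1 gave the same values, and leaving out replicate 2 gave an exact adjusted p of 0.0285 for both lists. Either omission also removes the sites of the Diagenode pair alone, so neither is separate support. None of 7 butyrophilins, 18 B cell identity genes, 10 T cell genes, 8 myeloid genes and 7 erythroid and liver genes was the nearest gene of a site within 10 kb of its TSS; sites credited to a neighbouring gene were not counted. EBF1, a transcription factor of the B lineage, had a site in 4 libraries at 46339 bp from its TSS, with the score 12.1.

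**Figure D2:**
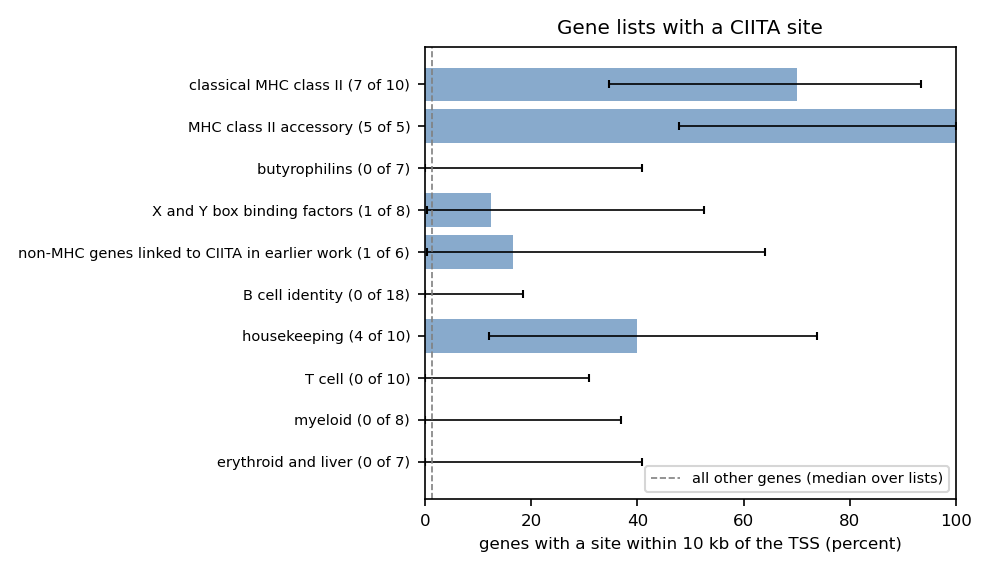
Share of the genes of each of 10 lists that were the nearest gene of a site of the series table within 10 kb of the TSS, in percent, with Clopper-Pearson 95% intervals; the dashed line is the share among all other genes. Bars reach 70% for the classical and 100% for the accessory MHC class II genes, and 40% for the housekeeping genes.

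Peak numbers varied between and within antibodies. Diagenode libraries had 1294.5 ± 1235 peaks (SD, n = 2) and Rockland libraries 101 ± 29.7 (SD, n = 2), a ratio of 12.8 that was 5.26 between the replicates numbered 1 and 17.8 between those numbered 2. With 2 libraries each, the smallest two-sided p an exact permutation test allows is 0.333, and no test was made. The Diagenode replicates themselves differed 5.15-fold. The ratio was 4.17 without Diagenode replicate 2 and 21.5 without Diagenode replicate 1.

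Lists made with different antibodies still marked the same places far more often than random placement. Diagenode replicate 1 shared 378 of 419 peaks with replicate 2 (90.2%, 95% interval 87.0 to 92.9%), and Rockland replicate 1 shared 33 of 78 with replicate 2 (42.3%, 31.2 to 54.0%). Rockland replicate 1 shared 39 of 78 peaks with the Boss Lab list and replicate 2 shared 58 of 120 (48.3%). The Rockland replicates shared 47.4% and 40.8% of their peaks with Diagenode replicate 2, and 30.8% and 18.3% with Diagenode replicate 1. Diagenode replicates 1 and 2 shared 7.64% and 4.94% with the Boss Lab list. All 10 pairs exceeded each of 1000 random placements (one-sided permutation p from the placements = 0.001, adjusted p = 0.001, the smallest they can give). Placement anywhere on a chromosome ignores where peaks of any ChIP library tend to lie. It therefore cannot tell shared CIITA sites from peaks unrelated to CIITA that recur in several libraries. In the first 50% of each list in file order, a setting chosen after the data were seen, the Rockland shares were higher. Rockland replicate 1 then shared 81.6% of its peaks with each of Rockland replicate 2, the Boss Lab list and Diagenode replicate 2, and 52.6% with Diagenode replicate 1. Rockland replicate 2 shared 78.0% with the Boss Lab list, 71.2% with Diagenode replicate 2 and 30.5% with Diagenode replicate 1. Same-antibody pairs averaged 35.2 percentage points above different-antibody pairs, without a test. A share of the shorter list depends on the lengths of both lists, which differ between pairs, so these averages are not like for like. The gap was 4.00 without Diagenode replicate 1 and 11.3 without replicate 2, and 66.2 and 62.1 without Rockland replicates 1 and 2, so it rested on the Diagenode pair.

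**Figure D3:**
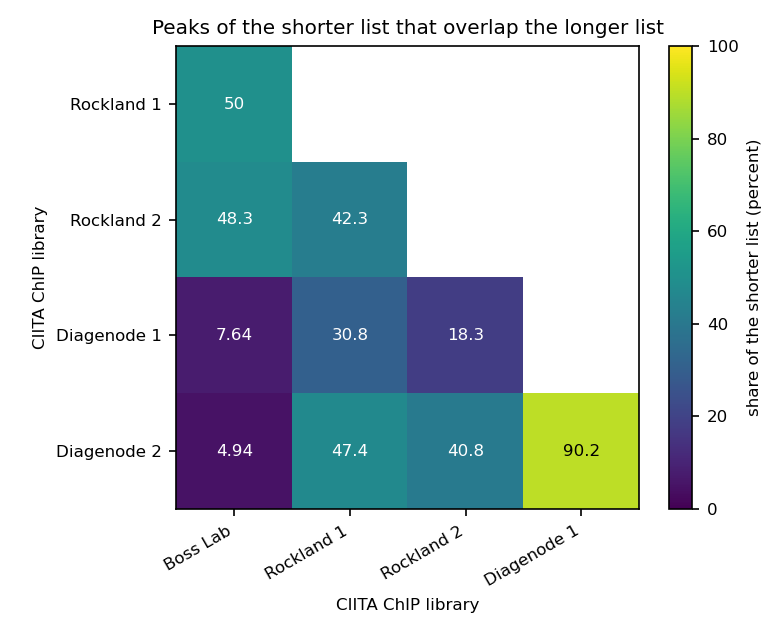
Share of the peaks of the shorter list, in percent, that overlap the longer list by at least 1 bp, for each pair of CIITA ChIP libraries without chromosome M. The Diagenode pair stands at 90.2%, and the pair of Boss Lab and Diagenode 2 at 4.94%.

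Merging gave 4494 sites, of which 4001 were found in 1 library, 437 in 2, 21 in 3, 15 in 4 and 20 in 5. Random placement of the lists gave a mean of 1.43 sites in 2 libraries and 0.001 in 3, and none in more, over 1000 draws. Here too, random placement cannot exclude peaks unrelated to CIITA that recur at the same places. All 32 table sites with peaks in both Rockland libraries also had peaks in the Boss Lab list and in Diagenode replicate 2. Merged sites that the table leaves out broke this pattern. The site at 51569864 to 51570062 on chromosome 11 had peaks in the Rockland libraries alone. That at 103 to 436 on chromosome M had peaks in the Rockland and Diagenode libraries but not in the Boss Lab list. The number of sites in 3 or more libraries, 56, was 37 without the Boss Lab library and 35 without Diagenode replicate 2.

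Sites in 3 or more libraries lay less often at promoters than sites in 2. Within 1 kb of a TSS lay 24 of 53 sites in 3 or more libraries (45.3%) and 371 of 427 sites in 2 libraries (86.9%), an odds ratio of 0.126 (95% interval 0.0649 to 0.241, two-sided Fisher's exact test, adjusted p = 8.84e-11). Most sites in 2 libraries came from the Diagenode pair alone, where 320 of 347 (92.2%) were promoters. The promoter odds ratio was 0.688 without Diagenode replicate 2 (Fisher's exact p = 0.481), where the call was lost, and 0.394 without replicate 1 (p = 0.0156).

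X and Y box scores were higher at sites of at least 2 antibodies than at sites with Diagenode peaks alone. No other sites of a single antibody had scores. The number of antibodies can therefore not be told apart from the Diagenode antibody in this contrast. The median score was 14 at 53 sites in 3 or more libraries and -3.18 at 426 scored sites in 2 libraries, a difference of 17.2 (bootstrap 95% interval 13.6 to 22.7). It was 5.93 at 132 scored sites of at least 2 antibodies and -3.98 at 347 sites with Diagenode peaks alone, a difference of 9.91 (8.52 to 14.2). Two-sided permutation tests gave p = 1e-05 for both, the smallest that 100000 permutations can give. Of the 426 sites in 2 libraries, 347 were those of the Diagenode pair alone, so the 2 contrasts overlap. Leaving out either Diagenode replicate removes these sites from the contrast by number of libraries. Its difference was then 14.8 (8.56 to 20.3, 45 against 86 sites) without replicate 1 and 15.8 (7.25 to 24.7, 33 against 39 sites) without replicate 2. A score above 10 stood at 56 of the sites of at least 2 antibodies and at 1 of those with Diagenode peaks alone, near SLC25A53. The ACTB, RPL13A, EEF1A1 and PPIA sites scored 4.65, -6.34, -8.13 and -9.54. Outside chromosome 6 the difference between these classes was 8.70 (5.81 to 9.99), and without the Boss Lab library it was 18.2. Both score comparisons were chosen after the scores of the library combinations had been seen, and the scale of the score is not given in the sources used here.

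**Figure D4:**
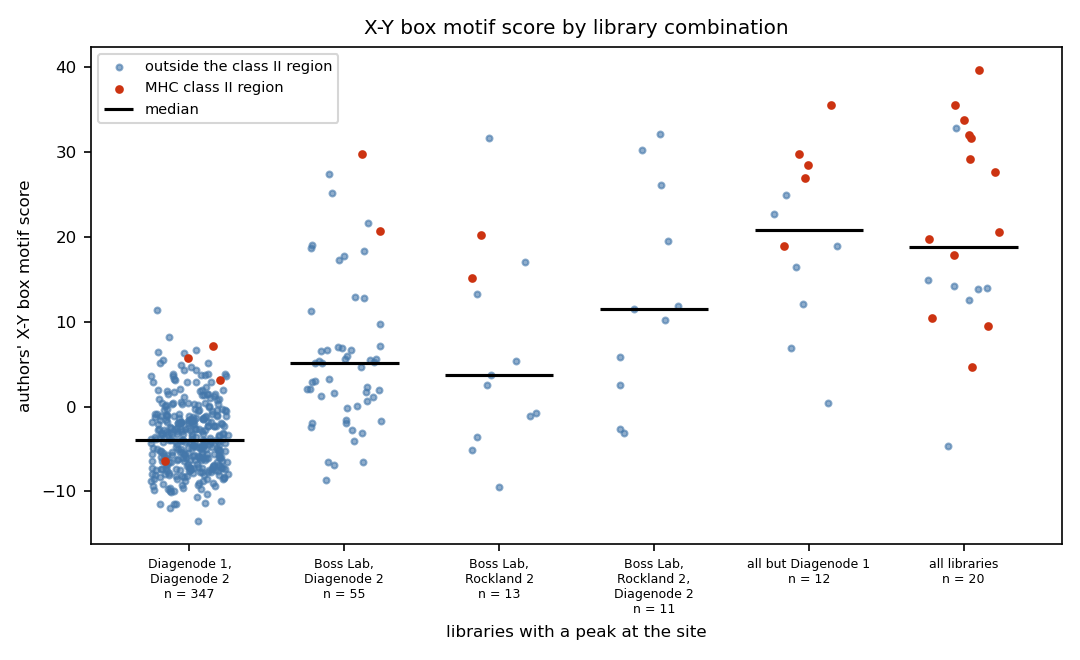
The authors' X-Y box motif score of each site by the libraries with a peak there, for combinations with more than 10 sites; points are spread sideways for legibility, lines are medians, and red points lie in the MHC class II region. Medians run from -3.98 for the Diagenode pair alone to 20.8 for the sites in all libraries but Diagenode replicate 1, with 18.8 for sites in all 5 libraries.

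Motif sequences at class II sites were in part nearly alike. At the HLA-DRA promoter the matched sequence was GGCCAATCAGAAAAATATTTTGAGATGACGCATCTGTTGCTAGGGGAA. The HLA-DRB1 promoter site (chromosome 6, 32557527 to 32557839) and the site 33825 bp from the HLA-DRA TSS (32441324 to 32441564) held the same sequence, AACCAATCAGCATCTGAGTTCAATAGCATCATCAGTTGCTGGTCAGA, with the score 35.5, and the HLA-DRB5 promoter motif lay 1 edit away.

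Outside the fixed lists, 25 further sites were taken in the order of the number of libraries and then of the score. In all 5 libraries lay sites nearest to C19orf81 (chromosome 19, 51182715 to 51182957, score 32.8), TTLL9, HIPK3, SBK2 and LOC101928358. The LOC101928358 site had the score -4.63 and a repetitive/CNV state in GM12878. Whether repeated sequence gave its peaks was not tested, so recurrence alone does not establish a CIITA site. In 4 libraries lay sites nearest to PARVG (1 bp from the TSS, score 24.9), SSC5D, HAUS5 (68 bp, score 18.9), TRIM26 (28 bp, score 16.4), LOC285819, SESN3 and TM4SF20. In 3 libraries lay those nearest to MYBPC2, ZNF672, ZFR2, PNRC2, TPP1, LOC643406, LOC644189, HEATR2, MKNK2, ENTPD3-AS1, INSIG1, MTO1 and NDUFS5, with scores from 30.2 at MYBPC2 to -2.08 at NDUFS5. The nearest gene is a matter of distance, up to 317982 bp for LOC101928358, and no expression was measured.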

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

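Signal outside the series table was counted after the data were seen. There were 13 merged sites in at least 2 libraries that the table leaves out, on chromosomes 4, 10, 11, 16, 21 and M, of which the sites at 42400368 to 42400576 on chromosome 10 and 103 to 436 on chromosome M had peaks in 4 libraries and that at 3179 to 3394 on chromosome M in 3. The 5 lists held 9 peaks on chromosome M, none of them in the Boss Lab list. No explanation was tested for either. No group had enough samples for a test of single outlying libraries.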

How the results depend on the processing

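Of 68 recomputed main results under alternatives, 61 counted as the same, 6 moved, 1 lost its call and 0 reversed. In tests, the same meant an unchanged direction and side of the threshold. For counts it meant a change within a fixed fold limit, and for other values one within the spread. That spread was wide for the peak number ratio, where 4.17 and 21.5 counted as the same as 12.8. For single pairs and lists the counts were 136 the same, 5 weaker and 8 stronger of 149. Score, first-part, local-move and same-antibody alternatives were chosen after the data were seen. With 1 library left out, the number of sites in 3 or more libraries ran from 35 to 54 and the promoter odds ratio from 0.0732 to 0.688. The gap between same- and different-antibody overlap ran from 4.00 to 66.2 percentage points. Fewer libraries alone lower the site count. Leaving out a Rockland or Diagenode replicate leaves 1 same-antibody pair, so the gap then rests on that pair. With either Diagenode replicate left out, the 347 sites of the Diagenode pair alone (92.2% promoters) drop out of the promoter comparison. Other causes of these changes were not tested. With the replicate number as a block, the Diagenode to Rockland ratio of peak numbers was 9.67 against 12.8. The 9.67 is a geometric mean and the 12.8 a ratio of arithmetic means. A ratio of geometric means without the block has the same value, so the change comes from the averaging and not from the block. The 2 replicate numbers cannot show whether they pair the libraries. All 10 pairs stayed past the threshold with an overlap of at least 50% of both peaks, with centres within 500 bp and under moves of 5 to 50 kb. Lists past the threshold numbered 4, and from 3 to 5 under alternatives. Not run were the alternatives on peak score (every score is 1, so a median filter removes nothing), promoters against single-library sites at recurrence 2, the motif search and the Raji against RJ2.2.5 settings. Leaving out a Diagenode library leaves no class of Diagenode peaks alone, so that score comparison has no such value. Unknown depth limits every count of peaks.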

Other observations

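The test of chromosome 19 and the comparison of list positions in replicate 2 or among sites in both Diagenode lists were chosen after earlier values were seen, and the score pattern itself was found in the same data. Some sites found in 2 libraries also had high scores. Sites nearest to FGF21 (chromosome 19, 49285752 to 49285960, score 21.6), PSMD3 (score 30.4), GART (38 bp from the TSS, score 18.7) and MARK3 (1 bp, score 19) were found with 2 antibodies in 2 libraries and carried scores in the range of class II promoters. HLA-L, an MHC class I pseudogene, and HCP5 on chromosome 6 had such sites with scores 18.3 and 12.9. These were named after their scores were seen. Inside the class II region, the promoters of BRD2, RXRB, VPS52 and DAXX had Diagenode peaks alone, with scores -6.42, 5.70, 7.11 and 3.15.

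Sites with Diagenode peaks alone had low X-Y box scores. Promoter location did not account for the gap, since among sites within 1 kb of a TSS the difference in medians was still 9.35 (95% interval 6.49 to 11.4, and 6.47 to 13.5 with other bootstrap draws, 75 against 320 sites). Lower sensitivity of the other antibodies could not be decided: in the Diagenode replicate 1 list, sites with Diagenode peaks alone stood 11.2 percentage points later than shared sites (-6.18 to 29.7), an interval that includes 0. In the replicate 2 list they stood 22.6 points earlier (difference -22.6, -32.9 to -11.0), but among sites with peaks in both Diagenode lists, 347 against 29, the difference was 4.06 (-1.15 to 6.69, permutation p = 0.08) there and 16.6 (1.19 to 31.8, permutation p = 0.07) in the replicate 1 list, and whether file order is a ranking is not known. A reaction of the Diagenode antibody with another protein at active promoters may also give such sites, which include ACTB and PPIA. That reaction was not tested, and the labels list no CIITA ChIP of RJ2.2.5.

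Recurrent sites clustered in the MHC class II region. Chance alignment of peaks placed independently in the region did not give this count. With the peaks of each library moved by 5 to 50 kb, the highest of 1000 draws gave 2 sites in 3 or more libraries against 19 observed. Such moves cannot exclude peaks unrelated to CIITA that recur at the same places in several libraries. Reads shared between class II paralogs stay open in part: 15.8% of the 19 motifs (3 of 19, at HLA-DRB1, HLA-DRB5 and the site 33825 bp from HLA-DRA) lay within 5 edits of another, below the bound set beforehand, but the interval reached 39.6%, above that bound. That an identical motif occurs at 2 sites was known before this bound was set. Recruitment of CIITA at X and Y boxes of these genes remains a hypothesis consistent with the scores.

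Sites shared between antibodies seemed to lie often on chromosome 19. Outside chromosome 6 it held 16 of 98 shared sites (16.3%) and 39 of 330 sites with Diagenode peaks alone (11.8%), an odds ratio of 1.45 (0.721 to 2.83, Fisher's exact p = 0.234). The interval included 1, so no difference between the classes was found, and one of up to 2.83-fold in odds is not excluded. The gene density of chromosome 19 was not measured. Over all chromosomes the promoter share was 56.4% for shared sites and 92.2% for Diagenode peaks alone. Whether gene density gives this number therefore stays open.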
